A study of Mus musculus with 6 samples.

How the data were processed

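Gene expression was measured in LSK cells sorted from the bone marrow of 3 adult mice, as YFP-positive (restored-labelled) and YFP-negative (knockdown-labelled) populations of each animal. Per the labels' protocols, RNA was prepared with a Qiagen kit, amplified and labelled with the NuGEN Ovation V2 system and hybridized to 3' expression arrays of Affymetrix. The deposited values are linear intensities of probe sets, summarized per array by the authors. Their summary, background and normalization method is not given in the sources used here. The values look scaled between arrays: the medians on the log2 scale lay between 7.24 and 7.44, and between 20 and 35 probe sets per array stood at 0. No count lies behind an array value, so no depth can be given, and the number of arrays limits the precision.

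The table holds 45101 probe sets, of which 64 controls were left out. A probe table with older annotation names 34945 of the rest by 1 gene symbol and 932 by several, and 9160 are unnamed here. Gene identifiers of 34741 of the 34945 matched the mouse gene table of assembly GRCm38.p6, and no symbol changed through it. Intensities were taken to log2(value + 16). Probe sets with a mean over the 6 arrays at or above the median, which is an intensity of 143, were kept (22519), and each gene was represented by its named probe set with the highest mean, which left 10824 genes. Because of the added 16, fold changes of dim genes are understated.

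The comparison was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) with the mouse as a fixed block, since the labels state that both populations came from the same animal. P-values were adjusted by Benjamini-Hochberg over all genes tested, with a threshold of 0.05. Gene lists were tested with camera at a preset correlation of 0.01, with Benjamini-Hochberg over the 28 lists, and beside it with an estimated correlation and with fry. With the mouse as a block, the arrays leave few residual degrees of freedom. The camera test with an estimated correlation rests on these, so it could hardly pass any list here. The lists held 868 entries, of which 78 had no named probe set, and at least 5 tested members were required. Erg was also tested with an exact two-sided sign-flip permutation over the 3 mice. Figures were drawn with matplotlib 3.10.9.

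The rule for named genes, the lists, the main design and most alternatives were fixed before the data were examined. The rule names Erg with every probe set, and 8 genes in each direction past the threshold and changed the same way in all 3 mice. Where too few pass, it names those with the smallest unadjusted p among genes changed the same way in all 3 mice. It also names the 2 members with the smallest unadjusted p of each list and 4 of each list past the threshold. A gene or count that an outlier or a disagreement singles out may be named outside the rule as chosen after its values were seen. The rule gave 81 distinct genes. Those among them that the report gives no value for are counted with their lists.

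The pairing was checked by correlating the deviations of arrays from their group means over the 10824 genes. Same-mouse correlations were 0.44 for mouse 278, -0.17 for mouse 279 and -0.29 for mouse 281. Between mice, the knockdown-labelled array of mouse 279 correlated at 0.34 with the restored-labelled array of mouse 281, and the restored-labelled array of mouse 279 at 0.41 with the knockdown-labelled array of mouse 281. The pairing comes from the labels and was kept. The transcripts of Kdm5d, Eif2s3y and Uty were present and Xist was low on all 6 arrays, so sex-linked genes could not tell the mice apart. With no replicate block 634 genes reached unadjusted p below 0.05, against 632 with it.

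The fit was tested on simulated arrays with known changes in 200 of 10824 genes, drawn 10 times with the means, mouse shifts and moderated spread of the real genes. It recovered 29.8% of 1.5-fold, 83.0% of 2-fold, 99.2% of 4-fold and 99.8% of 8-fold changes, and a list shifted by 0.5 was called in 10 of 10 runs. On average 11.2 unchanged genes and 0.4 other lists were called. The simulated noise was independent between genes, while members of real lists vary together (estimated correlation 0.50 for oxidative phosphorylation and 0.93 for mature neutrophil). The list results of the simulation therefore do not tell how often camera calls a list falsely in these data. The 200 changes were spread evenly over these sizes, and recovery with fewer changed genes was not simulated.

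The alternatives were no block, a random block, quantile normalization, centring on the median, no filter, a filter at the upper 30%, the mean over a gene's probe sets, each probe set on its own, eBayes with trend and robust settings, array weights, leaving out each mouse, added values of 1 and 64, a floor at 16, camera with an estimated correlation, fry, and lists without Erg. Chosen after seeing the data were a fit of 5 arrays without the restored-labelled array of mouse 279 and without the mouse term, a crossed block that exchanges the knockdown-labelled arrays of mice 279 and 281, and the lymphoid priming list without Ighm. Lists of plasma cell secretory genes, mature B cell surface genes and imprinted genes were also written after the first results were seen. The random block was not run for the lists, because camera takes no random block.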

Results

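Bone marrow hematopoietic stem and progenitor cells were compared between populations that differ in their labelled Erg dose. ERG is an ETS family transcription factor with a known part in the maintenance of hematopoietic stem cells. The mice carried 1 Erg knockdown allele, an interferon-inducible Cre recombinase and a Rosa26 reporter that turns on yellow fluorescent protein (YFP) where Cre has acted. YFP-positive cells are labelled as restored to the wild-type Erg level and YFP-negative cells as having about 40% less Erg. The sort was on YFP, so the labelled Erg dose cannot be told apart here from Cre action, the reporter or which cells Cre spared. Whether the reporter and the Erg allele recombined in the same cells was not measured here. Both populations were sorted from the same animal inside the LSK gate, which selects lineage-negative cells with Sca-1 and c-Kit on their surface. The data are 6 Affymetrix mouse genome arrays, 1 per population from each of 3 mice (278, 279 and 281). The mean intensity over all probe sets lay between 1031 and 1071 per array and the median probe set between 135 and 157, and the number of arrays limits the precision. Differences below are knockdown-labelled minus restored-labelled, on the log2(intensity + 16) scale, with the standard error of the paired limma fit.

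The first question was whether Erg itself differed between the sorted populations. The brighter of its 2 probe sets read 2764 ± 124 in the restored-labelled cells and 2810 ± 140 in the knockdown-labelled cells (SD, n = 3 arrays each). Its log2 difference was 0.024 ± 0.080 (adjusted p = 0.936, limma), and the single mice gave 0.12, -0.075 and 0.025. The 95% interval of this fit runs from -0.20 to 0.25, so the reduction nearest to the labelled 40% that it allows is 12.8%. The dimmer probe set read 1696 ± 159 against 1573 ± 245 (SD, n = 3 arrays each), a log2 difference of -0.11 ± 0.12 in a fit of every probe set that was negative in all 3 mice. Its interval, from -0.43 to 0.20, allows a fall of 25.9% at most. The exact two-sided sign-flip test over the 3 mice gave p = 0.75 and p = 0.25 for these probe sets, and 0.25 is the smallest p that 3 mice allow. The labelled reduction was therefore not seen at either probe set, and the groups are called knockdown-labelled and restored-labelled throughout. Which part of the transcript each probe set reads, relative to the altered part of the allele, was not analysed here, so whether these probe sets can read the change stays open. Recombination of the Erg allele in the sorted cells was also not measured here.

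**Figure D1:**
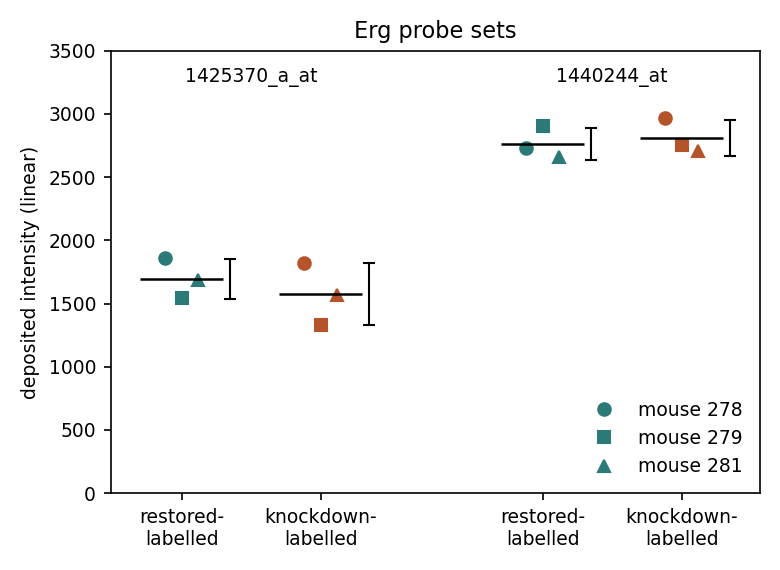
Deposited linear intensity (vertical axis) of both Erg probe sets on each of the 6 arrays, by labelled group (horizontal axis). Symbols are single mice, horizontal lines group means and bars 1 SD either side of the mean (n = 3); for the brighter probe set the means are 2764 and 2810, closer than the SD of 124 or 140.

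The second question was which genes differ between the populations labelled by Erg dose. Among 10824 genes, those with the smallest unadjusted p on the higher side included Fam241b, with a difference of 1.21 ± 0.087 (2.31-fold), and Ndn, an imprinted gene tied to stem cell quiescence, with 1.06 ± 0.095. The RNA-binding protein gene Cpeb3 differed by 0.70 ± 0.078, Gcsam, a germinal center signalling gene, by 0.66 ± 0.076, the surface receptor gene Slamf9 by 1.62 ± 0.20 and the transcription factor gene Zbed6 by 0.64 ± 0.079. Ppargc1a, a coactivator of mitochondrial biogenesis, differed by 1.04 ± 0.13 and Lrrn3 by 1.02 ± 0.13. On the lower side stood the carbonic anhydrase gene Car13 (-0.75 ± 0.10), the Eph receptor gene Ephb6 (-0.59 ± 0.083), the adaptor gene Sh2b2 (-0.57 ± 0.086) and Treml1, a receptor of platelet granules (-0.73 ± 0.12). The macrophage gene Aif1 (-0.97 ± 0.16), Osbpl7 (-0.44 ± 0.072), Cdr2l (-0.60 ± 0.10) and Zfp692 (-0.63 ± 0.11) followed. Other probe sets gave 0.033 and -0.15 for Car13, 0.040 for Osbpl7 and 0.43 for Ppargc1a. The lower group mean of Slamf9 (77.5), Lrrn3 (111), Ppargc1a (141), Aif1 (119) and Cdr2l (129) lay below the filter intensity of 143, so the sizes of these differences depend on the 16 added to each value. Each of these 16 genes differed the same way in all 3 mice, which the rule for naming them required. None of them passed the test, since the adjusted p of each was 0.771 in limma with Benjamini-Hochberg adjustment. No gene passed an adjusted p of 0.05 in either direction (0 higher, 0 lower). At unadjusted p below 0.05 there were 632 genes, 429 higher and 203 lower, where chance alone gives 541.2. The share that was higher, 67.9%, turned to 35.5% after quantile normalization and to 14.7% when each array was centred on its median, which moved the median of all genes to -0.11 from -0.00015. Without mouse 278 there were 258 such genes. On simulated arrays with 200 changed genes among 10824, the fit recovered 83.0% of 2-fold and 29.8% of 1.5-fold changes. Those arrays also held 4-fold and 8-fold changes, which ease the adjusted threshold. These shares therefore do not tell what would be found where few genes change, and Fam241b at 2.31-fold did not pass here.

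**Figure D2:**
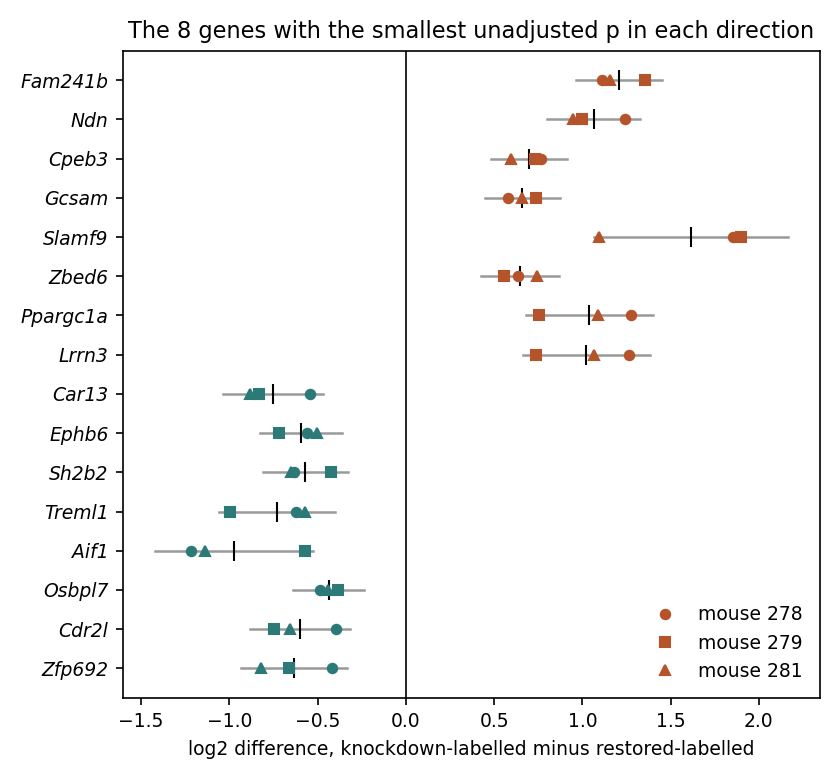
Log2 difference, knockdown-labelled minus restored-labelled (horizontal axis), of the 8 genes with the smallest unadjusted p in each direction, among genes that differed the same way in all 3 mice. Symbols are the 3 mice, vertical ticks the fitted difference and grey lines its 95% interval; Slamf9 reaches 1.62 and Aif1 -0.97, and no gene passed adjustment.

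A count that needs no estimate of spread took the genes at least 1.5-fold apart the same way in every mouse. There were 17 such genes, all higher in the knockdown-labelled cells, and 0 lower. Turning the sign of 1 mouse gave between 4 and 20 genes, so the count was not beyond the other sign patterns. Members from B-lineage biology were Ighm, the heavy chain of immunoglobulin M, at 2.14 ± 0.40, the transcription factor gene Irf4 at 2.37 ± 0.52, the B-cell receptor adaptor gene Blnk at 0.93 ± 0.17, and the plasma cell genes Mzb1 and Sdc1 at 1.44 ± 0.23 and 0.94 ± 0.17. Another probe set of Sdc1 gave 1.44. The tight junction gene Cldn5 stood at 1.95 ± 0.42. The restored-labelled means of Irf4 (85.2) and Cldn5 (72.0) lay below the filter intensity of 143, so the sizes of their differences depend on the 16 added to each value. The count was 5 in the upper 30% of probe sets, 46 with no filter on low values, and 79, 71 and 94 without mouse 278, 279 or 281, where fewer mice had to match. Groups without any overlap were found for 15.2% of genes, against 10% by chance for arrays that are not paired. With the labelled pairing, where 634 genes reached unadjusted p below 0.05 with no replicate block and 632 with it, 32.2% of genes had the same sign in all 3 mice against 25% by chance.

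The lymphoid priming list was higher in the knockdown-labelled cells. Of its 22 tested members 20 were higher, 8 of them at unadjusted p below 0.05, and the median difference was 0.27. The list passed in camera with a preset correlation (adjusted p = 8.00e-06, limma), and its medians in the single mice were 0.13, 0.24 and 0.29. With an estimated correlation the adjusted p = 0.821. Over 20 alternatives, 17 of which called the list, it ran from 2.54e-09 to 0.821, and without the restored-labelled array of mouse 279 and without the mouse term it was 0.0700. That array, which had the highest 3' over 5' log2 ratio (0.707), lay lowest in this list, with a median of -0.47 from the other arrays. The other 5 arrays lay between -0.26 and 0.30, and the groups interleaved. The restored-labelled array of mouse 278 (0.14) lay above the knockdown-labelled arrays of mice 279 (0.048) and 281 (0.11). Besides Ighm, Irf4 and Blnk, the T-lineage transcription factor gene Bcl11b differed by 0.83 ± 0.22. Of the 3 probe sets above the filter annotated to Ighm, the brightest gave 1.71, 3.23 and 1.48 in the 3 mice and another 1.63, 3.27 and 1.24, while the remaining one read 1968, 6143 and 82.6 in the restored-labelled cells and 100.3, 72.4 and 92.0, below the filter intensity of 143, in the knockdown-labelled cells. Several Ighm probe sets whose mean lay below the filter read 2856 to 5150 on the restored-labelled array of mouse 279. On every other array these read 14 to 51, so they went the other way in that mouse. Among other B-lineage genes, Mzb1 and Sdc1 passed when adjusted over the list alone (adjusted p = 0.0249 for both, limma) in the mature B cell and plasma cell list. That list had 5 members higher and 5 lower and did not pass in camera (adjusted p = 0.329).

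The megakaryocyte and platelet list was lower. Of 25 tested members 18 were lower, 4 of them at unadjusted p below 0.05, with a median of -0.098 (camera adjusted p = 0.0248). With an estimated correlation the adjusted p = 0.821. Over 20 alternatives, 16 of which called the list, it ran from 0.000407 to 0.846. Its leading members encode platelet surface or adhesion proteins: Treml1, the von Willebrand factor gene Vwf (-0.68 ± 0.13), and the glycoprotein genes Gp1bb (-0.61 ± 0.14) and Gp5 (-0.71 ± 0.25). Without mouse 281 the mean of the list was -0.053 instead of -0.15 and the adjusted p was 0.846, and without mouse 278 the mean was -0.26.

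The erythroid list was higher as a set, with 22 of 27 members higher and a median of 0.11 (camera adjusted p = 0.0413). With an estimated correlation the adjusted p = 0.821, with no replicate block it was 0.334, and with the crossed replicate block 0.0857. Without the restored-labelled array of mouse 279 and without the mouse term it was 0.203, with array weights 0.140, and in the upper 30% of probe sets 0.0895. Over 20 alternatives, 12 of which called the list, it ran from 0.000493 to 0.882. Its leading members went both ways: the metallothionein gene Mt2 at 0.52 ± 0.099, the heme synthesis gene Cpox at 0.33 ± 0.12 and the carbonic anhydrase gene Car1 at 0.25 ± 0.097, but the beta-globin gene Hbb-b2 at -0.39 ± 0.074. Without mouse 279 the mean of the list was -0.00094 (adjusted p = 0.882) instead of 0.16, and without mouse 278 it was 0.23. The difference of Hbb-b2 was 0.25 without the restored-labelled array of mouse 279 and without the mouse term. The granulocyte and monocyte list had 22 of 26 members lower and did not pass (adjusted p = 0.194, and 1.17e-10 to 0.828 over 20 alternatives), with the receptor genes Csf3r at -0.37 ± 0.13 and Csf1r at -0.40 ± 0.14. Its medians were -0.069, 0.44 and -0.63 in mice 278, 279 and 281. The granulocyte and monocyte list was called in 5 of the 20 alternatives: as lower without mouse 279, with array weights, with the crossed replicate block and with 5 arrays, and as higher without mouse 281. The mature neutrophil list gave medians of -0.048, 2.38 and -0.63.

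Genes of stem cell quiescence and of the ETS family were higher as sets. In the quiescence list 21 of 27 members were higher, with a median of 0.11 (camera adjusted p = 0.00515; adjusted p = 0.821 with an estimated correlation, and 0.000538 to 0.821 over 20 alternatives, of which 16 called it). Ndn led it, followed by the cell cycle inhibitor gene Cdkn1c (0.77 ± 0.22, from a restored-labelled mean of 133 that lies below the filter intensity), the transcription factor gene Foxo1 (0.28 ± 0.081) and the ubiquitin ligase gene Fbxw7 (0.34 ± 0.12). In the ETS family list 16 of 18 members were higher, with a median of 0.18 (camera adjusted p = 0.00515; adjusted p = 0.821 with an estimated correlation, and 0.00273 to 0.821 over 20 alternatives, of which 15 called it). Etv5 differed by 0.45 ± 0.073, Gabpa by 0.36 ± 0.12, Etv3 by 0.24 ± 0.087 and Erf by 0.23 ± 0.099. Without mouse 279 neither list passed, at adjusted p = 0.212 with a mean of 0.045 instead of 0.15 for quiescence and 0.160 with 0.082 instead of 0.17 for the ETS family. The restored-labelled array of mouse 279, which had the highest 3' over 5' log2 ratio (0.707), lay lowest in both lists, with a median of -0.25 from the other arrays in each. Without that array and without the mouse term neither list passed, at adjusted p = 0.196 for quiescence and 0.0707 for the ETS family. Without mouse 281 the mean of the quiescence list was 0.25. With centred arrays the means were 0.038 and 0.064.

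The long-term HSC list had 20 of 32 members higher and did not pass (adjusted p = 0.171), but it was called in 4 of 20 alternatives (0.00459 to 0.821). Vwf and Ndn, its leading members, lay on opposite sides. The list of stem cell transcription factors that partner with ERG had 11 of 18 members higher (adjusted p = 0.314), with Ikzf2 at 0.31 ± 0.087 (1.02 at another probe set) and Gfi1b at 0.23 ± 0.097. Its mean was -0.067 with centred arrays, and that of the long-term HSC list -0.063. Of 12 tested genes that neighbour Erg on its chromosome 8 were higher (adjusted p = 0.836), with Vps26c at -0.11 ± 0.080 and Get1 at 0.081 ± 0.074. With centred arrays the mean of this list was -0.076 and Get1 stood at -0.025.

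Mitochondrial and mitotic genes were lower as sets by small amounts, and the restored-labelled array of mouse 279, which had the highest 3' over 5' log2 ratio (0.707), lay highest in both sets. Its median was 0.13 from the other arrays in each, while the other 5 arrays lay between -0.045 and 0.0055 for oxidative phosphorylation and between -0.090 and 0.033 for G2 and M phase. In the oxidative phosphorylation list 45 of 51 members were lower, with a median of -0.055 and no member at unadjusted p below 0.05 (camera adjusted p = 0.00113). With an estimated correlation the adjusted p = 0.821, and over 20 alternatives, 18 of which called the list, it ran from 0.000275 to 0.821. The respiratory chain genes Cyc1, Uqcrc2, Ndufs7 and Ndufv1 gave -0.15 ± 0.071, -0.15 ± 0.071, -0.13 ± 0.079 and -0.13 ± 0.079. The mean of the list was -0.066, but -0.021 without mouse 279 and -0.11 without mouse 281, and its medians were -0.029, -0.14 and 0.00043 in the single mice. In the G2 and M phase list 29 of 46 members were lower, with a median of -0.058 (camera adjusted p = 0.0413). The adjusted p = 0.821 with an estimated correlation, and over 20 alternatives, 12 of which called the list, it ran from 0.00948 to 0.821. The spindle genes Dlgap5 and Kif2c gave -0.37 ± 0.086 and -0.25 ± 0.070, the mitotic kinase gene Plk1 gave -0.17 ± 0.076 and the cytokinesis gene Ect2 gave 0.24 ± 0.085. The list did not pass without mouse 278 (adjusted p = 0.328), without mouse 279 (0.0791), after quantile normalization (0.152), as the mean over a gene's probe sets (0.0519), with array weights (0.114) or with 5 arrays and no mouse term (0.0882). Its mean of -0.064 was -0.020 without mouse 279 and -0.11 without mouse 281. The S phase list had 29 of 41 members lower (adjusted p = 0.160, called in 2 of 20 alternatives), with Gins2 at -0.16 ± 0.088 and Hells at 0.14 ± 0.087. The MYC and ribosome biogenesis list had 30 of 38 lower (adjusted p = 0.0540), with Nop56 at -0.16 ± 0.098 and Ddx21 at 0.16 ± 0.073, whose other probe set gave -0.018. The blocking changed the call of the MYC and ribosome biogenesis list: its adjusted p was 0.0381 with no replicate block and 0.0155 with the crossed replicate block, and it ran from 0.000242 to 0.964 over 20 alternatives, of which 7 called the list.

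**Figure D3:**
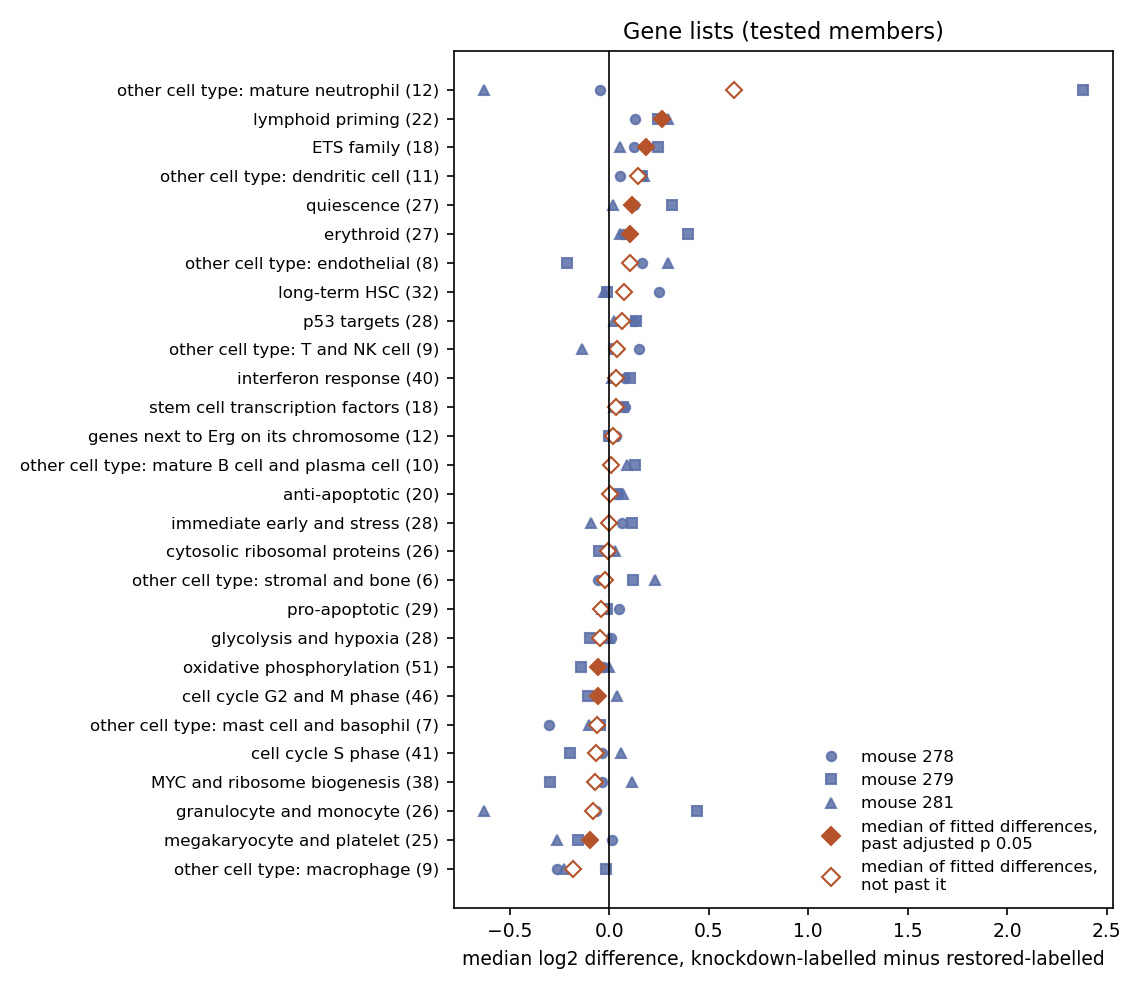
Median log2 difference, knockdown-labelled minus restored-labelled (horizontal axis), of 28 gene lists, with the number of tested members in brackets. Blue symbols are the medians in the 3 mice and diamonds the median of the fitted differences, filled for the 7 lists past adjusted p 0.05 in camera with a preset correlation; 0 lists passed with an estimated correlation, and the mature neutrophil list spans -0.63 to 2.38 between mice.

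The lists on cell death and stress did not pass in camera. The anti-apoptotic list had 11 of 20 members higher (adjusted p = 0.520), with Bag4 at 0.38 ± 0.12 and Cflar at 0.18 ± 0.082, and the pro-apoptotic list had 17 of 29 lower (adjusted p = 0.314), with Htra2 at -0.19 ± 0.069 and Casp1 at -0.25 ± 0.094. Other probe sets gave -0.18 for Bag4 and -0.018 and -0.13 for Cflar. For p53 targets 19 of 28 were higher (adjusted p = 0.171, called in 2 of 20 alternatives), led by Zmat3 at 0.29 ± 0.086. The interferon response list had 25 of 40 higher (adjusted p = 0.305), with Oas3 at 0.25 ± 0.077 and Rtp4 at 0.18 ± 0.070. Immediate early and stress genes were split evenly, 14 higher and 14 lower (adjusted p = 0.769), with Fosl2 at 0.29 ± 0.086 and Dusp5 at 0.31 ± 0.12. Their mean of -0.057 and median of -0.0026 were negative while camera ranked them as higher. The glycolysis and hypoxia list had 19 of 28 lower (adjusted p = 0.329), although P4ha1 stood at 0.27 ± 0.071 and Aldoc at 0.31 ± 0.090, and another probe set of P4ha1 gave -0.17. Cytosolic ribosomal protein genes had 15 of 26 lower (adjusted p = 0.442), with Rpsa at -0.083 ± 0.077 and Rpl12 at -0.37 ± 0.43, which ran from -0.87 to 0.17 without a mouse. With centred arrays the means of the anti-apoptotic, p53 and interferon lists were negative, at -0.079, -0.018 and -0.051.

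Markers of other cells that a sort can carry were measured the same way, and none of these lists passed in the labelled pairing of all 6 arrays with the filter and scaling used here. The mature neutrophil list had 9 of 12 members higher (adjusted p = 0.228), with Ngp at 1.04 ± 0.67 and Cd177 at 0.84 ± 0.73, which ran from -0.10 to 1.65 without a mouse. The neutrophil list was called in 5 of 20 alternatives, as lower without mouse 279 (mean -0.40) and as higher without mouse 278 (0.71), without mouse 281 (1.12), with centred arrays (0.37) and with the crossed replicate block (0.48). Its adjusted p ran from 6.42e-05 to 0.884. The dendritic cell list was called in 2 alternatives and the macrophage, B cell and plasma cell, endothelial and stromal lists in 1 each. The macrophage list had 7 of 9 lower (adjusted p = 0.314), with the complement gene C1qb at -1.39 ± 0.33 and the kinase gene Axl at 0.20 ± 0.12. All 7 mast cell and basophil markers were lower (adjusted p = 0.194), Cpa3 by -0.31 ± 0.098 and Ms4a2 by -0.18 ± 0.16, which ran from -0.33 to 0.018 without a mouse. For T and NK cells 6 of 9 were higher (adjusted p = 0.836), with Cd3e at 0.86 ± 0.42 and Thy1 at -0.42 ± 0.21. Among dendritic cell markers 7 of 11 were higher (adjusted p = 0.194), with Zbtb46 at 0.66 ± 0.16 and Ly6d at 1.39 ± 0.42. Endothelial markers were split, 4 higher and 4 lower (adjusted p = 0.314), with Cldn5 and Vwf on opposite sides. The stromal and bone list had 4 of 6 lower, with a median of -0.021 and a mean of 0.037 (adjusted p = 0.562), with the chemokine gene Cxcl12 at 0.26 ± 0.077 and Sparc at 0.12 ± 0.11. Another probe set of Cxcl12 read 119 in the restored-labelled cells, below the filter intensity, and 648 in the knockdown-labelled cells, and was higher in all 3 mice. With centred arrays the means of the T and NK cell list and of the stromal list were -0.033 and -0.070.

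In all, 7 of the 28 lists passed in camera with a preset correlation, 4 higher and 3 lower. With an estimated correlation 0 passed, and in fry, which asks whether a set moves on balance one way, 0 passed (smallest adjusted p = 0.359). The test with an estimated correlation has few residual degrees of freedom, so its 0 says little against a single list. The estimated correlations of the lists that passed ran from 0.040 (ETS family) to 0.50 (oxidative phosphorylation). These lie above the preset 0.01, so the calls at the preset value are not secured either. Without the restored-labelled array of mouse 279 and without the mouse term, 4 lists passed, and without mouse 281 there were 12. Adjusted over the list alone, limma called Ndn in the long-term HSC and quiescence lists, 2 genes in the mature B cell and plasma cell list, 4 in the endothelial list and 0 in each of the other lists. In the endothelial list these were Vwf, Cldn5, Emcn and Flt4, of which Emcn and Flt4 were named after their values were seen.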

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

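Of the tests here, those of neutrophil-lineage RNA and of mature B cells, the dimmer plasma cell and B cell markers, the fit of 5 arrays, the crossed block and the list without Ighm were chosen only after the results were seen. The readings of the mature B cell test and of the scaling test for the array of mouse 279 were also changed after their values were seen. Groups of 3 arrays are too small for a test of single outlying values, and none was run.

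The first pattern is that the arrays labelled mouse 279 and mouse 281 did not vary together within a mouse, and with the crossed replicate block 988 genes reached unadjusted p below 0.05 instead of 632, with 0 past adjustment in limma. Probe sets that set 1 pair of arrays apart from the other 4, with a gap of at least 1 log2 unit and a spread of at most 0.5 in each set, as an allele carried by 1 mouse would, numbered 16 in the matching that crosses these mice, 13 in the next of the 15 matchings and 5 in the labelled one. All 5 of the labelled matching come from mouse 278, which the crossed matching shares, and 9 of the 16, which the matching with 13 shares, come from the knockdown-labelled array of mouse 279 with the restored-labelled array of mouse 281. Of these 9, Stx3 (named after its values were seen) stood at 7.64 and 7.52 on these arrays and at 10.97 to 11.10 on the other 4, but Chil3 is a mature neutrophil gene, that list lay highest on the same arrays (medians of 1.67 and 1.23 from the others), and the granulocyte and monocyte medians were 0.16 and 0.29 there against -0.30 and -0.33 on the other crossed arrays. An exchange of the mouse numbers of 2 arrays within 1 group is thus a candidate explanation, since the mice are labelled as a mixed background in which alleles can differ, but 4 such probe sets also joined the restored-labelled arrays of mice 278 and 279, a myeloid share of RNA common to the crossed arrays and the group that would hold an exchange stay open, and no biological explanation was tested.

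The second pattern is that the restored-labelled array of mouse 279 stands apart, with the lowest mean correlation to the other arrays (0.963) and a score of 30.7 on the first principal component, which carried 39.9% of the variance. After quantile normalization this correlation was still the lowest, at 0.962 against 0.970 for the next array. The reading set beforehand would count this against scaling between arrays as the source of the low correlation. However, the correlation hardly moves with scaling (0.963 before and 0.962 after), so this test cannot decide. By a reading set after the values were seen, scaling stays open. The component score of this array was not recomputed. The mean 3' over 5' log2 ratio of its actin and Gapdh control probe sets was 0.707, outside the 0.471 to 0.540 of the other 5 arrays, so degraded or poorly amplified RNA may contribute. Its mature neutrophil genes lay at a median of -1.31 from the other arrays, below all 10000 random lists matched on level. Those lists were drawn gene by gene, while the neutrophil genes vary together (estimated correlation 0.93), so this rank carries little weight. A lower share of neutrophil-lineage RNA may contribute too, although both arrays of mouse 278 were also low (-0.67 and -0.79). The lineage-negative gate is meant to remove mature neutrophils, but how well it did was not tested. Degraded or poorly amplified RNA and a lower neutrophil share were not told apart, and a biological difference of that population was not tested.

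The third pattern is that lymphoid priming genes were higher in the knockdown-labelled cells. Scaling between arrays is argued against by the mean of the list, which was 0.52 after quantile normalization against 0.56 before (camera adjusted p = 2.00e-06), and without Ighm it was 0.49. The adjusted p of the list ran from 2.54e-09 to 0.821 over 20 alternatives of camera and fry. In camera it was 0.0700 in the fit of 5 arrays, which drops both the restored-labelled array of mouse 279 and the mouse term. The lost call can therefore not be credited to that array alone, which stands apart and lay lowest in this list at -0.47. Plasma cells carried in the sort stay open: 14 secretory genes had a mean of 0.16 (0.24, 0.58 and -0.35 in the 3 mice) and a median of -0.048, with 4 higher and 10 lower. The single-mouse means lean on Prg2 (-2.06, 3.27 and -3.84). Most of the 14 start from a high level (median 11.34 on the log2 scale) that would hide a small share. Pou2af1 (3.66, 3.07 and 0.059) and Tent5c (1.96, 1.53 and 0.19), whose mean levels lie lower, were higher in all 3 mice. Prg2, Pou2af1 and Tent5c were named after their values were seen. Among 6 dimmer plasma cell markers Tnfrsf17, Derl3 and Eaf2 were higher in all 3 mice. Mature B cells stay open for the same reason, with a mean of -0.13 over 7 genes whose levels lay between 11.35 and 12.55 on the log2 scale, although 6 dimmer B cell markers gave means of 0.39, -0.16 and -0.10 in the 3 mice, and 1 of them was higher in all mice; the dimmer markers of both cell types lie below the filter on low values and decide nothing, and a first reading had counted the -0.13 against mature B cells. A biological difference of the knockdown-labelled cells, which the design names, was not tested and stays open, with no fall of Erg seen at its probe sets. The lineage-negative gate is meant to remove mature cells, but whether either cell type passed it was not tested. The brightest probe sets of Igha (7907 to 14130) and Igk (8966 to 15499) read high on all 6 arrays.

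The other splits of the arrays are too few for a share under 0.05. With 632 genes at unadjusted p below 0.05 in the real split, 4 of the 10 splits gave as many and the highest other gave 2488. With the mouse as a block, a split that parts only 1 mouse rests on the difference within that mouse. The 2488 rests on mouse 279, whose restored-labelled array stands apart. With no replicate block the real split gave 634 genes and the splits with 2488 gave 425 and 436. The highest other split with no block, which parts all 3 mice, gave 786 genes, and another gave 679. Only the 4 splits that part all 3 mice have the form of the real one. With the mouse as a block, 2 of these, the real one included, gave as many genes, with 650 as the highest other. For lists, the real split gave 7, 6 of the 10 splits gave as many and the highest other gave 11, and of the 4 that part all 3 mice 2 gave as many. With the mouse as a block, camera called the lymphoid priming list in the real split and in 5 of the other splits. Of the 3 others that part all mice 1 called it, at camera adjusted p = 1.87e-05 against 8.00e-06. With no replicate block the camera adjusted p was 0.000281 in the real split and as low as 3.01e-07 in another split. For genes at least 1.5-fold apart in every mouse, the real pattern gave 17, 3 of the 4 sign patterns gave as many and the highest other gave 20. These patterns are also too few for a share under 0.05.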

How the results depend on the processing

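The 5-array fit, the crossed block and the list without Ighm were chosen only after the results were seen. The count of genes past adjusted p 0.05 was 0 in limma under all 18 alternatives, with the smallest adjusted p between 0.135 and 0.831. The genes at unadjusted p below 0.05 (632) numbered 971 with centred arrays, 1083 with no filter (more genes tested), 1369 with each probe set on its own (more features tested), 988 with the crossed replicate block and 258 to 723 without a mouse. Higher and lower genes were 429 and 203, against 252 and 458 after quantile normalization and 143 and 828 with centred arrays. Genes at least 1.5-fold apart in every mouse (17) numbered 46 with no filter, 5 in the upper 30%, 27 with 1 added, 28 with the floor and 71 to 94 without a mouse, where only 2 mice had to match. Lists past the threshold (7) numbered 14 with centred arrays, 0 with an estimated correlation, 0 in fry, 4 with 5 arrays and no mouse term and 6 to 12 without a mouse. With no replicate block (7 lists) or a random block (634 genes) neither count moved by over 1.5 times, and with no replicate block the erythroid list lost its call and MYC and ribosome biogenesis gained one. The difference of Erg (0.024) was -0.083 with centred arrays, -0.045 as the mean over its probe sets, -0.11 at the other probe set and -0.025 to 0.073 without a mouse, never past the threshold. Of 1377 values of other named genes under the alternatives, 1364 kept direction and 13 reversed. No gene passed in any setting, so the side of the threshold could not change. The genes were named for a small unadjusted p in these same data, so a kept direction carries little weight. Those that reversed were Get1 with centred arrays (-0.025) and Hbb-b2 with 5 arrays (0.25). Other probe sets reversed for Car13 (0.033), Osbpl7 (0.040), Ighm (-3.36, against knockdown-labelled values below the filter), Bag4 (-0.18), Cflar (-0.018 and -0.13), Ddx21 (-0.018) and P4ha1 (-0.17). Without a mouse, Ms4a2 (-0.33 to 0.018), Rpl12 (-0.87 to 0.17) and Cd177 (-0.10 to 1.65) reversed. Of 140 values of the 7 called lists, 106 kept the call, 33 lost it and 1 reversed, and of 416 values of the other lists, 366 stayed uncalled in the same direction, 27 gained a call and 23 reversed. With centred arrays the mean was negative for long-term HSC (-0.063), stem cell transcription factors (-0.067), anti-apoptotic (-0.079), p53 targets (-0.018), interferon response (-0.051), T and NK cell (-0.033), stromal and bone (-0.070) and neighbours of Erg (-0.076), beside a median of all genes of -0.11; long-term HSC and p53 targets passed camera there as higher, since it ranks lists against other genes. A list was counted as reversed by the sign of its mean, a rule set after the first table was seen. Stromal and bone was -0.043 after quantile normalization, and immediate early and stress 0.10 in the upper 30%. With 5 arrays, S phase (0.025), MYC and ribosome biogenesis (0.021), ribosomal proteins (0.0059) and stromal and bone (-0.0018) reversed. Without a mouse, the means ran from -0.11 to 0.13 for long-term HSC, -0.47 to 0.27 for granulocyte and monocyte, -0.00094 to 0.23 for erythroid, -0.039 to 0.019 for pro-apoptotic, -0.12 to 0.031 for S phase, -0.17 to 0.044 for MYC and ribosome biogenesis, -0.15 to 0.062 for immediate early and stress, -0.052 to 0.013 for ribosomal proteins, -0.40 to 1.12 for mature neutrophil and -0.0020 to 0.10 for stromal and bone. The random block was not run for lists. Where no cause is named, the cause was not tested. Probe sets near the filter, at an intensity of 143, are also limited by signal over background.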

Other observations

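The genes and probe sets in this part were chosen after their values were seen, except where a list named them before, and the resampling in the test of imprinted genes was added after its percentile was seen. Beyond the B-lineage genes, the 17 genes at least 1.5-fold higher in every mouse included Hmga2, a chromatin protein gene of fetal stem cell programs, at 0.83 ± 0.12, the ion transport regulator gene Fxyd1 at 1.56 ± 0.21, Gpr25 at 0.95 ± 0.19 (both from restored-labelled means below the filter intensity of 143, at 92.1 and 103), Wfdc18 at 1.14 ± 0.34 and the noncoding imprinted transcript Airn at 1.34 ± 0.32. None passed adjustment (limma adjusted p = 0.771 for each).

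Some immunoglobulin probe sets were bright on the arrays of both sorted populations, and which cells carried these transcripts was not tested. The brightest Igha probe set read 7907 to 14130 on the 6 arrays with a difference of -0.017 and an SE of 0.12 between groups, and the brightest Igk probe set read 8966 to 15499 with 0.43 and an SE of 0.16. Kappa variable region probe sets differed from array to array: 11 of 17 spanned more than 3 log2 units over the 6 arrays, and 4 of those 11 differed the same way in all 3 mice. Igkv6-15 read 5060 and 7970 on the knockdown-labelled arrays of mice 278 and 279, but 394 on that of mouse 281, which is below the 1482 of its restored-labelled partner array.

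One probe set annotated to Igkv9-120 read 807, 366 and 641 in the restored-labelled cells and 20.8, 14.2 and 20.4 in the knockdown-labelled cells of mice 278, 279 and 281 (limma adjusted p = 0.759 over all 45037 probe sets). The latter values lie far below the filter intensity of 143, so no fold is given. What its probes match, the reporter included, was not analysed here, so whether it reads an immunoglobulin gene stays open. With 16 added to each value it was the only probe set at least 4-fold apart the same way in all 3 mice, where other sign patterns gave 1 to 4 probe sets. Another probe set of Igkv9-120 read 19.9, 2030 and 1766 in the restored-labelled cells and 13.3, 23.4 and 2649 in the knockdown-labelled cells.

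A hypothesis from Ndn, Cdkn1c and Airn, which are imprinted genes, was that imprinted genes were higher as a group. The 21 other tested imprinted genes had a median of 0.050, at percentile 87.5 of 10000 random lists matched on level, with 11 higher and 10 lower. Resampling the members put that percentile anywhere from 10.5 to 99.96, so the test left the hypothesis open. Igf2r, whose locus also carries Airn, stood at 0.97 ± 0.23 and Grb10 at 0.37 ± 0.12.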
